A study of Mus musculus with 10 samples.

How the data were processed

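Gene expression was measured in splenic B cells, sorted by FACS as B220+CD22+ cells, on 10 Affymetrix Mouse Gene 1.0 ST arrays. Per the labels, 3 arrays came from wild-type mice, 3 from mice with a floxed Sca1-Bcl6 transgene (called floxed here) and 4 from mice in which this transgene had been exposed to mb1-Cre (called delta here). The transgene was built from a mouse Bcl6-IRES-eGFP cassette between loxP sites in a Ly6a (Sca1) vector. The labels do not say whether each array stands for a separate animal, nor which transgenic line, sex, age or hybridization date belongs to which array. The p-values therefore measure the spread between these samples.

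The deposited values are the authors' RMA intensity for each probe set. They lie on a linear scale, from 4.46 to 26808, and not on a log2 scale, so log2 of each value was taken. RMA corrects for background, normalizes between arrays and summarises probes into probe sets. Its version, the software that ran it and the genome build of the probe annotation are not given in the sources used here. The tables held 34760 probe sets, of which 21640 carried exactly 1 gene symbol, 1321 carried several and 11799 carried none. Probe sets with exactly 1 symbol were kept, and for the 954 genes with several such probe sets the probe set with the highest mean over all 10 arrays was used, which left 19937 genes. Ly6a itself and some members of the gene lists were not analysed here, because no probe set with a single symbol carried them. The depth of an array has no counting error, so the number of arrays limits the precision.

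Differences were estimated with limma 3.58.1 in R 4.3.3, by lmFit with a mean for each of the 3 groups over all 10 arrays and eBayes without trend or robust options. The prior had 4.32 degrees of freedom, which gave 11.3 in total. The 3 contrasts were floxed against wild-type, delta against wild-type and delta against floxed, all two-sided, with Benjamini-Hochberg adjustment over 19937 genes and a threshold of 0.05. Standard errors (SE) and 95% confidence intervals (CI) of log2 changes come from this fit, and standard deviations (SD) are those between arrays of a group. A gene was called non-overlapping when every array of a group lay beyond every array of the other group.

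Before the data were examined, 24 gene lists were fixed: 19 for B cell states, pathways and cell programmes, and 5 for other cell types that a sort could retain (T cell, NK cell, myeloid, erythroid and plasmacytoid dendritic cell). Of these, 23 had at least 5 measured members and were tested with camera from limma at a preset correlation between genes of 0.01. The immunoglobulin constant region list had 3 of its 12 members measured and was not tested. Camera was also run with a correlation estimated for each list, and fry from limma was run as a further set test. Lists were adjusted by Benjamini-Hochberg within a contrast, and members were also counted as past the threshold when adjusted over the list alone. A planned look at the spread of immunoglobulin V genes was void, since 9 such probe sets were measured and at least 20 were required.

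Named genes followed a rule fixed before the data were examined. It names Bcl6, Ly6a and Cd79a in each comparison, and the 12 largest rises and 12 largest falls among genes past the threshold with non-overlapping groups, leaving out predicted genes. It also names up to 4 members of each list past the threshold, or else up to 2 members as values only, and, where fewer than 10 genes were called, the 5 smallest p-values in each direction as values. Xist, Eif2s3y, Kdm5d, Uty, Zfp979, Col6a4, Cpne4 and Gm7265 lie outside this rule and were chosen after their values were seen.

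The sex of the mice was read from the arrays. An array was given a male pattern when the mean of the Y-linked genes Eif2s3y, Kdm5d and Uty lay above Xist, and a female pattern otherwise. The fit with sex as a covariate had 6 residual degrees of freedom in place of 7. Because the wild-type arrays are all of female pattern and the floxed arrays all of male pattern, this fit compares delta arrays with wild-type arrays of female pattern, delta with floxed arrays of male pattern, and floxed with wild-type through the difference between delta 1 and the other delta arrays.

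Alternatives to the normalization (quantile normalization again, centring on array medians), the filter on dim genes, the gene unit, the variance prior, array weights, the fold threshold, the arrays in the fit and a replicate block, and leaving out each array in turn, were fixed before the data were examined. The mean of the T cell list per array as a covariate, a fit with floxed replicate 2 as the sole floxed array, and sex as a covariate were added after seeing the data. The overlap of both comparisons against wild-type was set beside 100 simulations of unchanged groups that share the same wild-type arrays. Gene order along chromosomes came from a RefSeq gene table and was used for neighbours only.

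The procedure was tested on simulated data with 19937 genes, 200 of them changed, in 10 runs. Each value was drawn from a normal distribution with the moderated spread of its gene, without correlation between genes and without outlying arrays. Recovery in the real arrays may therefore be lower than the shares given here. It recovered 89.1% of 1.5-fold changes and 98.8% of 2-fold changes in floxed against wild-type, with a false share of 4.86% among the calls. The corresponding recovery of 1.5-fold changes was 92.5% in delta against wild-type and 92.7% in delta against floxed. With sex as a covariate, 1.5-fold changes were recovered at 28.8% in floxed against wild-type, 88.4% in delta against wild-type and 54.8% in delta against floxed. At 2-fold the corresponding shares with sex as a covariate were 87.8%, 97.6% and 95.7%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.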

Results

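The data were 10 expression arrays of splenic B220+CD22+ B cells, with 3 wild-type, 3 floxed and 4 delta arrays. The median RMA intensity per array lay between 139 and 145. Correlations across genes lay between 0.993 and 0.997 for arrays of the same group and between 0.989 and 0.996 for arrays of different groups. The axis of largest variation took 28.7% of the variance and placed wild-type arrays at 12.6 to 16.9, delta arrays at -7.03 to 6.28 and floxed arrays at -16.2 to -11.7.

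The groups differed in the sex pattern of their arrays. Xist, the RNA that silences an X chromosome in female cells, had log2 levels of 12.84 to 13.04 in 6 arrays and 5.38 to 6.20 in the other 4. Eif2s3y, a Y-linked translation factor gene, had log2 levels of 3.71 to 3.99 in those 6 arrays and 9.88 to 10.39 in the other 4. The Y-linked demethylase gene Kdm5d lay at 5.22 to 5.62 against 9.02 to 9.55, and its relative Uty at 4.58 to 4.84 against 9.16 to 9.71. A male pattern was present in 0 of 3 wild-type arrays, 3 of 3 floxed arrays and 1 of 4 delta arrays (delta 1). Sex and genotype thus coincide in floxed against wild-type, and a correction for sex rests on delta 1 alone. Xist, Eif2s3y, Uty and Kdm5d differed between delta 1 and the other delta arrays. So did Zfp979 on chromosome 4, by -4.06 on the log2 scale, and Col6a4 and Cpne4 on chromosome 9, by -1.75 and -2.10. With 1 delta array of male pattern, an effect of sex cannot be told apart there from other traits of that array. Xist itself was -7.27 on the log2 scale in floxed against wild-type (SE 1.42, adjusted p = 0.0520), since the delta group holds both patterns and widens its shared spread.

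Bcl6, the transcriptional repressor that the transgene carries, was measured first as a check of the labels. Its probe set (10438738) had a mean RMA intensity of 1086 ± 299 (SD, n = 3) in wild-type, 942 ± 51 (SD, n = 3) in floxed and 837 ± 80 (SD, n = 4) in delta arrays. The log2 change of Bcl6 in floxed against wild-type was -0.17 (SE 0.15, 95% CI -0.51 to 0.16, adjusted p = 0.688), and in delta against wild-type it was -0.35 (SE 0.14, adjusted p = 0.578). Bcl6 in delta against floxed was -0.17 (SE 0.14, adjusted p = 0.870). The Bcl6 probe set does not separate transgenic from endogenous transcripts, and no excess of Bcl6 RNA was detected in these mature B cells. Wild-type replicate 1 had the highest Bcl6 intensity (1430), and without it the change in floxed against wild-type was 0.04 and that in delta against wild-type was -0.13.

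Cd79a, which encodes the signalling chain Ig-alpha of the B cell receptor and is the mb1 locus that drives Cre, fell in delta arrays. Its probe set (10551025) had a mean intensity of 10433 ± 351 (SD, n = 3) in wild-type, 9876 ± 494 (SD, n = 3) in floxed and 7470 ± 157 (SD, n = 4) in delta arrays. In delta against wild-type the change of Cd79a was -0.48 on the log2 scale (SE 0.06, 95% CI -0.61 to -0.36, adjusted p = 0.0427), and all 4 delta arrays lay below all other arrays. The direct difference between delta and floxed was -0.40 (95% CI -0.53 to -0.28) with an adjusted p of 0.123, and floxed against wild-type gave -0.08 (adjusted p = 0.628). The change of Cd79a in delta against wild-type was -0.49 with sex as a covariate (SE 0.06, adjusted p = 0.0677), which for this comparison is the same fit as without delta replicate 1. The call also ended without delta replicate 3, without floxed replicates 1 or 3 and without wild-type replicates 1 or 2 (adjusted p = 0.0688, 0.0659, 0.0519, 0.129 and 0.211), with log2 changes between -0.49 and -0.46. It ended as well with the 2 groups alone in the fit (adjusted p = 0.0784), with every probe set kept (adjusted p = 0.129) and with floxed replicate 2 as the sole floxed array (adjusted p = 0.0784).

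**Figure D1:**
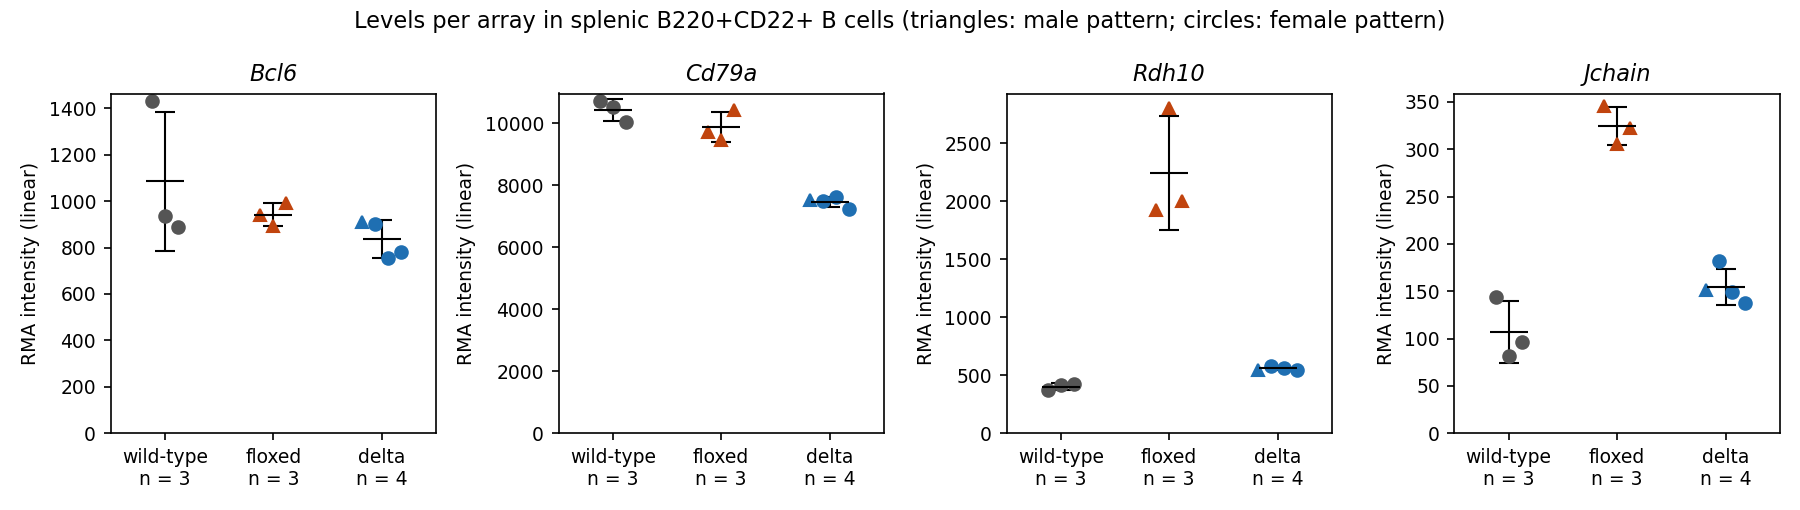
RMA intensity (linear axis) of Bcl6, Cd79a, Rdh10 and Jchain on each of 3 wild-type, 3 floxed and 4 delta arrays, with triangles for arrays of male pattern, circles for arrays of female pattern, and a bar for the mean with its SD. Cd79a is lowest in the delta arrays, with a mean of 7470, and Rdh10 is highest in the floxed arrays, with a mean of 2244.

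Floxed against wild-type arrays addressed what differs in B cells of mice that carry the intact transgene. The rise with the smallest p was in Rdh10 (probe set 10344952), which encodes a retinol dehydrogenase of retinoic acid synthesis. Its intensity went from 402 ± 30 (SD, n = 3) in wild-type to 2244 ± 489 (SD, n = 3) in floxed, a 5.51-fold rise (log2 2.46, SE 0.12, adjusted p = 6.29e-06). Tbx21, the transcription factor T-bet, rose 4.32-fold (log2 2.11, SE 0.32, adjusted p = 0.0171). The chemokine receptor gene Cxcr3, a known T-bet target, rose 4.11-fold (log2 2.04, SE 0.25, adjusted p = 0.00945).

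Further rises were in Nt5e, which encodes the ectonucleotidase CD73 (log2 2.37, SE 0.40, adjusted p = 0.0308), and in the inhibitory receptor gene Lilrb4a (log2 2.08, SE 0.34, adjusted p = 0.0282). Fgl2, a fibrinogen-like protein gene, rose by 2.51 (SE 0.43, adjusted p = 0.0337). Nr3c2, the mineralocorticoid receptor, rose by 1.73 (SE 0.25, adjusted p = 0.0171), and Rcn3, a calcium-binding protein of the secretory pathway, by 1.69 (SE 0.20, adjusted p = 0.00945). Jchain, which joins polymeric IgM and IgA and is typical of plasma cells, rose 3.12-fold (log2 1.64, SE 0.17, adjusted p = 0.00383), from an intensity of 107 ± 33 to 325 ± 20 (SD, n = 3 each). The remaining named rises were Glt28d2 at 1.44, Trabd2b at 1.35 and Art3 at 1.32 on the log2 scale, with adjusted p of 0.0132, 0.0147 and 0.0460.

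The largest named fall was in Cecr2, a chromatin remodelling factor gene (log2 -2.11, SE 0.21, adjusted p = 0.00368). Dhrs3, which encodes a retinaldehyde reductase and so acts against the direction of Rdh10, fell as well (log2 -1.89, SE 0.26, adjusted p = 0.0153). Its level in delta 1, of male pattern, was 7.09, within the floxed range of 6.82 to 7.30, against 7.91 to 8.44 in the other delta arrays. Rdh10 had no such step, at 9.09 in delta 1 against 9.09 to 9.18 in the others. Part of the fall of Dhrs3 therefore cannot be told apart from sex. Cd93, a surface marker of immature and transitional B cells, changed by -1.58 (SE 0.26, adjusted p = 0.0282). The ubiquitin ligase genes Mid1 and Nedd4 changed by -1.46 and -1.03 (adjusted p = 0.0340 and 0.0171). Bmf, a pro-apoptotic BH3-only gene, changed by -1.04 (adjusted p = 0.0282), and the cyclin-dependent kinase gene Cdk6 by -0.82 (adjusted p = 0.0171). The phosphodiesterase gene Pde2a changed by -1.05 (adjusted p = 0.0113) and Csrp2 by -0.96 (adjusted p = 0.0171). Mir15a, the gene of a microRNA that targets Bcl2, changed by -0.91 (adjusted p = 0.0239). Edaradd at -0.88 and Hmgcll1 at -0.84 completed the named falls, with adjusted p of 0.0153 and 0.0445.

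**Figure D2:**
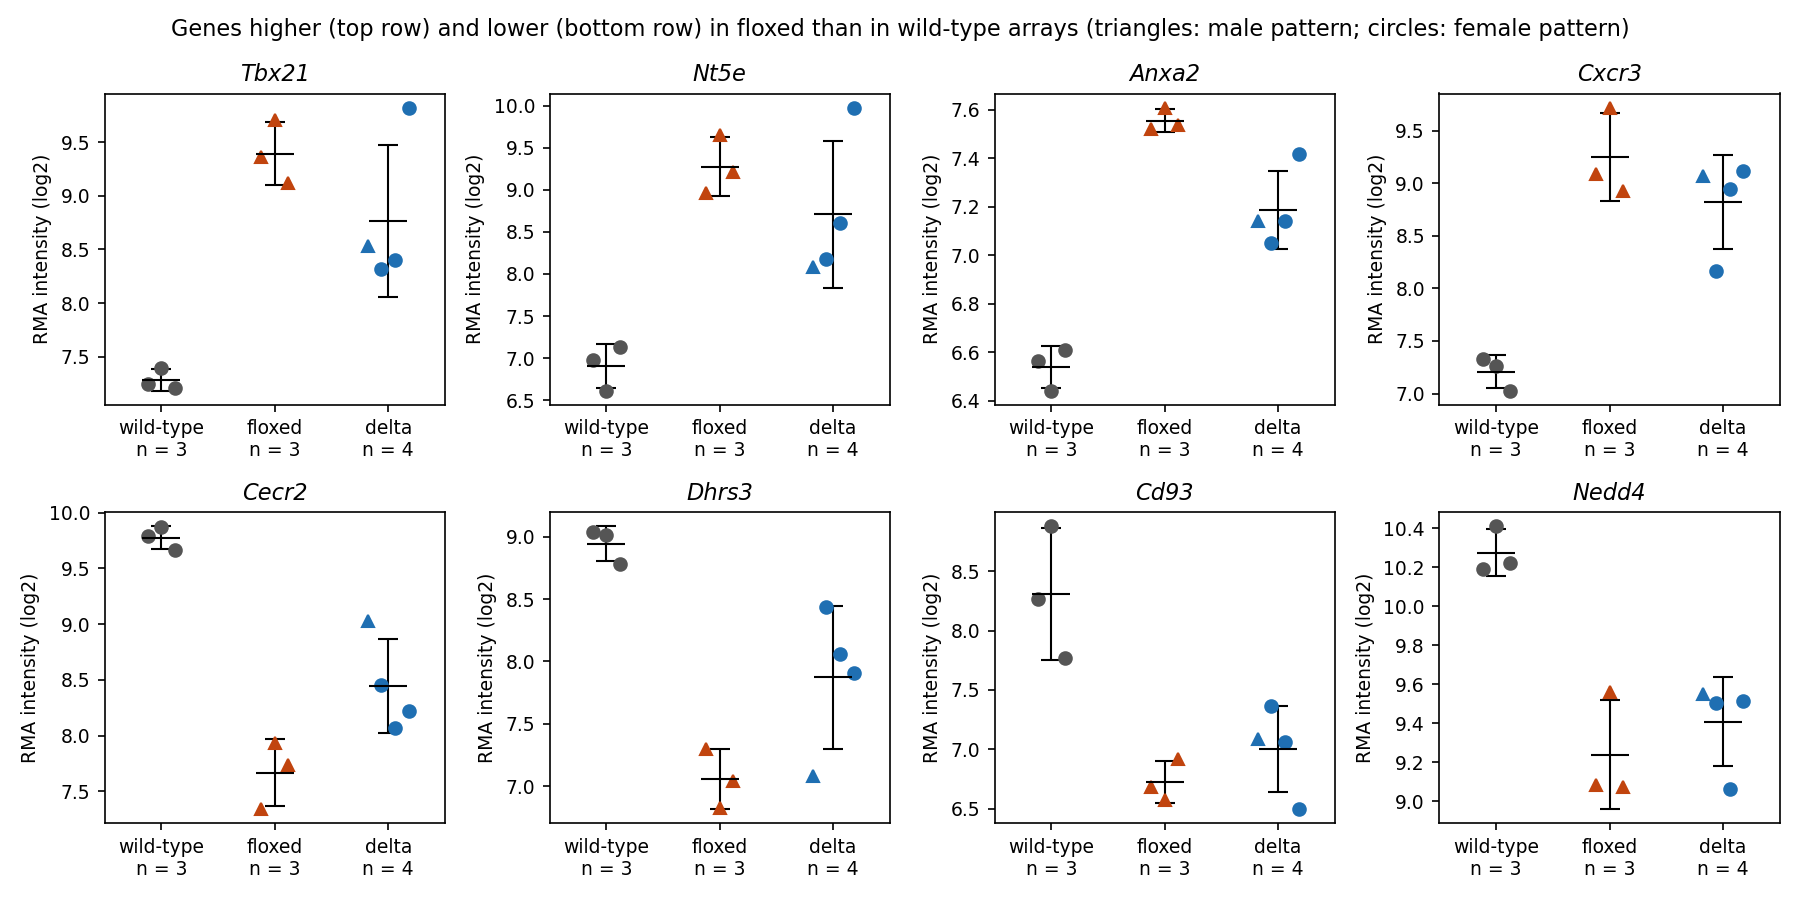
RMA intensity on a log2 axis of 4 genes higher (Tbx21, Nt5e, Anxa2 and Cxcr3) and 4 genes lower (Cecr2, Dhrs3, Cd93 and Nedd4) in floxed than in wild-type arrays, with a point per array (triangles for male pattern, circles for female pattern) and a bar for the mean with its SD. The delta mean lies between both other means in each panel, which the choice of these genes on the floxed change favours. The Tbx21 level of delta 4 (9.82) stands above the other delta arrays (8.31 to 8.53). The Dhrs3 level of delta 1, of male pattern, (7.09) lies among the floxed arrays (6.82 to 7.30) and below the other delta arrays (7.91 to 8.44).

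In all, limma called 110 of 19937 genes in floxed against wild-type, 78 higher and 32 lower, of which 32 changed at least 2-fold. All 110 had non-overlapping groups, as did 16.7% of all genes where 10% would by chance. With sex as a covariate 2 genes passed, Rdh10 (2.50, SE 0.22) and Cecr2 (-2.89, SE 0.25), both with an adjusted p of 0.00336, and 1450 genes had an unadjusted p under 0.05. All 110 kept their direction at a median of 0.990 of their former change, but their SE grew by a median of 1.79 times, because the correction rests on delta 1. Genes in which delta 1 differs from the other delta arrays have a wide shared spread and were less likely to be called, as with Xist. The kept direction and size of the 110 therefore say little about sex. The estimates of single genes moved apart, Nt5e to 3.21 (SE 0.65), Tbx21 to 2.43 (SE 0.57) and Dhrs3 to -0.84 (SE 0.26). The count was 46, 37 and 25 without floxed replicates 1, 2 and 3, 24 and 18 without wild-type replicates 1 and 2, and 67 and 240 without delta replicates 3 and 4. Among the 29 named genes, Rdh10, Cxcr3, Rcn3, Jchain, Cecr2 and Anxa2 kept their calls whichever array was left out.

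Among the fixed gene lists, that of marginal zone, B1 and age-associated B cells had the smallest camera p in floxed against wild-type. Of its 20 measured genes 5 rose, 0 fell and 15 did not pass, with 11 past the threshold when adjusted over the list alone, and the median log2 change was 0.75. Anxa2, which encodes a membrane-binding annexin, rose by 1.02 (SE 0.09, adjusted p = 0.00180), Fcrl5 by 1.07 (adjusted p = 0.0282) and the checkpoint receptor gene Ctla4 by 0.78 (adjusted p = 0.0282), beside Tbx21 and Nt5e. Camera called the list (adjusted p = 1.21e-12), with an adjusted p of 0.0747 with an estimated correlation. In the same arrays the T cell list, which shares Cd5 with this list, had a mean of 0.54, 0.005 and 0.38 above wild-type in floxed 1, 2 and 3, against 0.78, 0.76 and 0.61 for the marginal zone, B1 and age-associated B cell list.

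The plasma cell and secretory pathway list had 20 measured genes, of which Jchain rose, Sdc1, the plasma cell marker CD138, fell (-0.51, adjusted p = 0.0450) and 18 did not pass, with 4 higher and 1 lower when adjusted over the list alone. Its median change was 0.18, and camera called it higher (adjusted p = 1.81e-05, and adjusted p = 0.0747 with an estimated correlation). The pro-B and pre-B cell list had a median of -0.14 over 14 genes, with Cd93 lower, 13 not past the threshold and 4 lower when adjusted over the list alone. Camera called it lower (adjusted p = 0.000283, and adjusted p = 0.0747 with an estimated correlation). The glycolysis list had 0 of 13 genes past the threshold in limma and 6 higher when adjusted over the list alone, with Pfkp at 0.32 (adjusted p = 0.0585) and Aldoa at 0.25 (adjusted p = 0.0981). Its median was 0.18 and camera called it higher (adjusted p = 1.32e-07, and adjusted p = 0.0747 with an estimated correlation).

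The MYC and ribosome biogenesis list was called higher, with a median of 0.17, no member of 19 past the threshold, 1 past it when adjusted over the list alone, and Ncl at 0.23 (adjusted p = 7.84e-08, and adjusted p = 0.160 with an estimated correlation). The proliferation list was called higher with a median of 0.10 over 25 genes, none of them past either threshold (adjusted p = 0.000233, and adjusted p = 0.149 with an estimated correlation). In it Mcm2 was at 0.24 and Top2a at 0.39, with -0.54 in a second Top2a probe set. The list of BCL6-repressed genes was called higher with a median of 0.27 over 18 genes, 2 higher and 1 lower when adjusted over the list alone (adjusted p = 0.000256, and adjusted p = 0.129 with an estimated correlation). Its member Cd80, a costimulatory ligand, was at 1.74 (adjusted p = 0.0909) and Irf7 at -0.36 (adjusted p = 0.150). The NF-kappaB target list was called higher with a median of 0.08 over 15 genes, 3 higher when adjusted over the list alone, with Traf1 at 0.77 and Cd83 at 0.72 (adjusted p = 0.000353, and adjusted p = 0.160 with an estimated correlation). The MHC class II list was called higher with a median of 0.15 over 10 genes, 1 higher when adjusted over the list alone, with H2-Oa at 0.48 (adjusted p = 0.000483, and adjusted p = 0.160 with an estimated correlation).

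The type I interferon response list was called lower with a median of -0.36 over 17 genes, of which 10 were lower and 2 higher when adjusted over the list alone. Mx2 was at -0.61 (adjusted p = 0.132) and Oasl1 at -0.36 (adjusted p = 0.134), and the list had a camera adjusted p of 0.00202 and an adjusted p of 0.222 with an estimated correlation. The member Rsad2 went the other way, at log2 levels of 9.09 to 9.53 in floxed against 7.57 to 8.33 in wild-type arrays. The germinal centre list was called higher with a median of 0.11 over 16 genes, 1 higher when adjusted over the list alone, with Basp1 at 0.48 and Fas at 0.70 (adjusted p = 0.00387, and adjusted p = 0.207 with an estimated correlation). The p53 target list was called higher with a median of 0.08 over 14 genes, 1 higher when adjusted over the list alone, with Zmat3 at 0.53 (adjusted p = 0.0265, and adjusted p = 0.160 with an estimated correlation). The immediate early and stress list was called higher with a median of 0.37 over 17 genes, 1 higher when adjusted over the list alone, with Hspa1a at 2.29 and Btg2 at -0.28 (adjusted p = 0.0160, and adjusted p = 0.551 with an estimated correlation). This list turned with sex as a covariate, to a mean of -0.38 and a median of -0.46, since delta 1 lay 0.99 above wild-type.

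Of the other lists 7 were not called in floxed against wild-type. The mature follicular list had a median of -0.06 (camera adjusted p = 0.373), with Cd72 at 0.68 and Fcer2a at -0.34. B cell receptor signalling had a median of 0.01 (adjusted p = 0.373), with Bcl10 at -0.16 and Btk at -0.14. In the chromatin list Hdac1 rose by 0.44 (adjusted p = 0.0179), 18 of 19 genes did not pass, and the list median was -0.09 (adjusted p = 0.166). The haematopoietic stem and progenitor list had a median of -0.01 and a mean of 0.07, opposite in sign (adjusted p = 0.361), with Flt3 at 1.02 (adjusted p = 0.0558) and Hoxa5 at 0.47. The pluripotency list had a median of -0.05 and a mean of 0.03, again opposite in sign (adjusted p = 0.783), with Myc at 0.63 and Klf4 at 0.47. The myeloid list had a median of 0.05 (adjusted p = 0.259), with the macrophage gene Adgre1 at 1.91 (adjusted p = 0.0809) and Ltf at 0.30. The plasmacytoid dendritic cell list had a median of -0.03 while camera ranked it upward (adjusted p = 0.732), with Ccr9 at 0.68 and Cd300c at -0.21.

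Markers of other cells were also higher in floxed arrays. The erythroid list was called with a median of 0.58 over 10 genes, none past the threshold and 6 when adjusted over the list alone (adjusted p = 1.23e-06, and adjusted p = 0.157 with an estimated correlation), with Car1 at 0.56 and Trim10 at 0.82. Its mean was 0.79, 0.52 and 0.32 above wild-type in floxed 1, 2 and 3. The T cell list was called with a median of 0.18 over 16 genes, 1 past the threshold when adjusted over the list alone (adjusted p = 1.24e-05, and adjusted p = 0.207 with an estimated correlation), with Cd3d at 0.42 and Cd28 at 0.44. The NK cell list was called with a median of 0.22 over 13 genes, 2 past the threshold when adjusted over the list alone (adjusted p = 5.88e-05, and adjusted p = 0.160 with an estimated correlation), with Prf1 at 0.81 and Il2rb at 1.40. Its mean was 0.64, 0.12 and 0.49 above wild-type in floxed 1, 2 and 3. With floxed 2 as the sole floxed array, whose spread is then assumed from the other groups, camera ranked the T cell and NK cell lists downward at means of 0.005 and 0.12 (adjusted p = 0.972 and 0.922), and 6 genes passed the threshold in floxed against wild-type. With the T cell mean as a covariate 10 genes passed, Rdh10, Jchain, Cecr2 and Anxa2 among them, while smaller changes with wider SE left Tbx21 at 1.86 (SE 0.40, adjusted p = 0.164) and Nt5e at 2.16 (SE 0.52, adjusted p = 0.205).

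In total camera called 16 of 23 lists in floxed against wild-type, 14 higher and 2 lower. With an estimated correlation camera called 0 lists, with 7 at an unadjusted p under 0.05, and fry called 4, namely plasma cell, pro-B and pre-B cell and glycolysis (adjusted p = 0.0132 each) and marginal zone, B1 and age-associated B cell (adjusted p = 0.0137). List calls ended without wild-type replicate 3 for MHC class II, germinal centre and immediate early genes (adjusted p = 0.0505, 0.131 and 0.166), and without floxed replicate 2 for germinal centre, immediate early and p53 genes (adjusted p = 0.0632, 0.0696 and 0.0840). They also ended without wild-type replicate 1 for immediate early and p53 genes (adjusted p = 0.0917 and 0.117) and without floxed replicate 3 for p53 genes (adjusted p = 0.0604). The mean of the T cell list was 0.19 without floxed replicate 1 and 0.31 with all arrays. The germinal centre mean was 0.13 with all arrays, 0.20 and 0.06 without floxed replicates 1 and 2, and 0.25, 0.08 and 0.06 without wild-type replicates 1, 2 and 3. The p53 mean was 0.07 without wild-type replicate 1 against 0.11, and the MHC class II mean was 0.09 without wild-type replicate 3 against 0.16.

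Sex as a covariate left 12 lists called in floxed against wild-type, 9 higher and 3 lower. The calls ended for BCL6-repressed genes (median 0.09, adjusted p = 0.225), NF-kappaB targets (median 0.06, adjusted p = 0.447), p53 targets (median 0.04, adjusted p = 0.447) and MHC class II genes (median 0.10, adjusted p = 0.0581), and the immediate early list turned. The mean of the erythroid list went from 0.54 to 1.02, that of the germinal centre list from 0.13 to 0.08 and that of the interferon list from -0.17 to -0.11. The marginal zone, B1 and age-associated B cell list had a median of 0.77 in that fit (adjusted p = 4.48e-09, and adjusted p = 0.233 with an estimated correlation).

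Delta against wild-type arrays addressed what differs in B cells of mice whose transgene had met mb1-Cre. Nr3c2, the mineralocorticoid receptor, rose 3.13-fold (log2 1.65, SE 0.23, adjusted p = 0.0441) in 4 of 4 delta arrays. Cxcr3 rose by 1.62 (SE 0.23, adjusted p = 0.0444) and Pltp, a phospholipid transfer protein gene, by 1.09 (SE 0.15, adjusted p = 0.0441). Rcn3 rose 2.82-fold (SE 0.19 on the log2 scale, adjusted p = 0.0427). The p38-family kinase gene Mapk12 rose by 0.77 (adjusted p = 0.0491) and Anxa2 by 0.65 (SE 0.08, adjusted p = 0.0427). Cecr2 was the largest fall (log2 -1.33, SE 0.20, adjusted p = 0.0491).

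Beside Cd79a, the other falls in delta arrays were Edaradd at -0.76 (adjusted p = 0.0491), Tmem26 at -0.68 (adjusted p = 0.0444), the Wnt pathway gene Frat1 at -0.58 (adjusted p = 0.0441) and the membrane trafficking gene Ehd2 at -0.55 (adjusted p = 0.0427). Dmwd at -0.46, the ubiquitin-conjugating enzyme gene Ube2e3 at -0.42 and the predicted gene Gm7265 at -0.92 completed the list, with adjusted p of 0.0441, 0.0491 and 0.0491. In all, limma called 15 genes, 6 higher and 9 lower, of which 5 changed at least 2-fold, and 1574 genes had an unadjusted p under 0.05. All 15 had non-overlapping groups, as did 9.25% of all genes where 5.71% would by chance.

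With sex as a covariate, which sets delta 2, 3 and 4 against wild-type, 3 genes of the delta comparison passed, Pltp at 0.94, Cecr2 at -1.53 and Nr3c2 at 1.83 (adjusted p = 0.0323, 0.0122 and 0.0312), and all 15 kept their direction at a median of 0.983 of their former change. A difference of delta 1 from the other delta arrays also widens the spread in the fit that chose these 15 genes. Their kept size therefore says little about sex. No gene passed in limma without delta replicate 3, floxed replicate 1, floxed replicate 3, wild-type replicate 1 or wild-type replicate 2, where 1546, 1603, 1756, 1313 and 1340 genes had an unadjusted p under 0.05. The count was 3 without delta replicate 1 (for this comparison the same fit as that with sex), 9 without floxed replicate 2 and 23 without wild-type replicate 3.

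The type I interferon response list was called lower in delta arrays, with a median of -0.40 over 17 genes, none past the threshold and 11 lower when adjusted over the list alone (adjusted p = 9.97e-10, and adjusted p = 0.146 with an estimated correlation). Its members Usp18 and Ifit2 were at -0.60 (adjusted p = 0.167) and -0.45 (adjusted p = 0.177). The pro-B and pre-B cell list was called lower with a median of -0.18 over 14 genes and 3 lower when adjusted over the list alone (adjusted p = 0.000179, and adjusted p = 0.146 with an estimated correlation), with Cd93 at -1.30 and Lef1 at -0.61. In the marginal zone, B1 and age-associated B cell list Anxa2 rose and 19 of 20 genes did not pass, with 8 higher when adjusted over the list alone and a median of 0.39 (adjusted p = 1.80e-07, and adjusted p = 0.231 with an estimated correlation). The mean of this list was 0.85 above wild-type in delta 4 and 0.28, 0.18 and 0.27 in delta 1, 2 and 3, while the T cell list mean was 0.20 in delta 4 and -0.08, -0.11 and -0.07 in the others. Without delta replicate 4 the mean change of the marginal zone, B1 and age-associated B cell list was 0.24, against 0.39 with it.

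The MYC and ribosome biogenesis list was called higher with a median of 0.13 (adjusted p = 1.80e-07, and adjusted p = 0.231 with an estimated correlation), with Gnl3 at 0.25. The immediate early list was called higher with a median of 0.35 (adjusted p = 1.14e-05, and adjusted p = 0.294 with an estimated correlation), with Dusp1 at 0.81. Its mean was 0.42 and fell to 0.22 without delta replicate 1, which lay 0.99 above wild-type against 0.10, 0.09 and 0.48 in delta 2, 3 and 4. The NF-kappaB list was called higher with a median of 0.13 (adjusted p = 0.000179, and adjusted p = 0.231 with an estimated correlation), with Traf1 at 0.59. The glycolysis list was called higher with a median of 0.07 (adjusted p = 0.000602, and adjusted p = 0.231 with an estimated correlation). The list of BCL6-repressed genes was called higher with a median of 0.02 and a mean of 0.28, 6 higher and 1 lower when adjusted over the list alone (adjusted p = 0.0128, and adjusted p = 0.231 with an estimated correlation), with Myc at 0.90 and Gpr183 at 0.65. The plasma cell list was called higher with a median of 0.07, 2 higher and 1 lower when adjusted over the list alone (adjusted p = 0.0246, and adjusted p = 0.231 with an estimated correlation), with the chaperone gene Hspa5 at 0.28. The MHC class II list was called higher with a median of 0.09 (adjusted p = 0.0246, and adjusted p = 0.417 with an estimated correlation). The p53 list was called higher with a median of 0.05 (adjusted p = 0.0455, and adjusted p = 0.231 with an estimated correlation).

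Camera thus called 11 lists in delta against wild-type, 9 higher and 2 lower. With an estimated correlation it called 0, with 3 at an unadjusted p under 0.05, and fry called the interferon and the pro-B and pre-B cell lists (adjusted p = 0.0313 each). Calls ended without wild-type replicate 2 for BCL6-repressed, MHC class II, p53 and plasma cell genes (adjusted p = 0.0782, 0.113, 0.0782 and 0.268), without wild-type replicate 3 for MHC class II genes (adjusted p = 0.714), and without delta replicates 2 or 4 for plasma cell genes (adjusted p = 0.0542 and 0.0561). The p53 call also ended without delta replicates 1 or 4, floxed replicates 1, 2 or 3 and wild-type replicate 1 (adjusted p = 0.0504, 0.104, 0.0582, 0.0529, 0.0961 and 0.248). The p53 mean of 0.11 was 0.07 without delta replicate 4 and 0.07 without wild-type replicate 1. The plasma cell mean of 0.08 was 0.03 without wild-type replicate 2, and the MYC mean of 0.14 was 0.09 without it. The MHC class II mean of 0.07 was 0.15 without wild-type replicate 1 and 0.007 without wild-type replicate 3. In the fit with sex 12 lists were called, without p53 genes (adjusted p = 0.0504) and with the mature follicular list lower (adjusted p = 0.0297, and adjusted p = 0.335 with an estimated correlation) and the erythroid list higher (adjusted p = 0.00821, and adjusted p = 0.373 with an estimated correlation). Among lists not called, the mature follicular list held Cd79a as its fallen gene and 19 not past the threshold, with a median of -0.05 (adjusted p = 0.0785). The chromatin list had a median of -0.05 (adjusted p = 0.0963) with Hdac1 at 0.32 and Ezh2 at -0.41. The myeloid list had a median of -0.02 and a mean of 0.09 (adjusted p = 0.706), with Adgre1 at 1.35. The plasmacytoid dendritic cell list had a median of -0.01 (adjusted p = 0.690), with Tlr7 at -0.33. Proliferation had a median of -0.08 (adjusted p = 0.0900), germinal centre 0.005 (adjusted p = 0.0963) and pluripotency 0.01 (adjusted p = 0.205). Stem and progenitor genes had a median of 0.002 (adjusted p = 0.367) and B cell receptor signalling 0.01 (adjusted p = 0.536). The T cell, erythroid and NK cell lists had medians of -0.05, 0.09 and -0.003 (adjusted p = 0.926, 0.215 and 0.868), and camera ranked the NK cell list upward against its median.

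Both comparisons against wild-type shared 12 called genes, all in the same direction. The 5 higher genes were Cxcr3, Nr3c2, Rcn3, Pltp and Anxa2, and the 7 lower genes were Cecr2, Gm7265, Edaradd, Tmem26, Ehd2, Frat1 and Dmwd. Independent lists of these sizes would share 0.0235 higher and 0.0144 lower genes, but both lists rest on the same wild-type arrays. In 100 simulations of unchanged groups a mean of 0.04 higher and 0.05 lower genes were shared. Those simulations called a mean of 0.41 higher and 0.37 lower genes in floxed, and 0.19 and 0.18 in delta. They could therefore share few genes by construction and do not test the overlap. Over the 110 genes called in floxed against wild-type, the delta change had a median of 0.639 of the floxed change. Because the wild-type arrays enter both comparisons, and the 110 genes were chosen on the floxed change, this ratio and the sign of the delta changes say little by themselves. The correlation of both changes across genes was 0.729 against a simulated mean of 0.503. Simulated correlations reached 1 and genes are not independent replicates, so no conclusion is drawn from this difference. Mapk12, Ube2e3 and Cd79a were called in delta alone, with adjusted p of 0.865, 0.783 and 0.123 for the direct difference from floxed.

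The overlap was 0 without delta replicate 3, floxed replicates 1 or 3 or wild-type replicates 1 or 2, where limma called no gene in delta against wild-type. It was 3 without delta replicate 1 and 21 without wild-type replicate 3. A single gene, Cecr2, was shared with sex as a covariate.

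**Figure D3:**
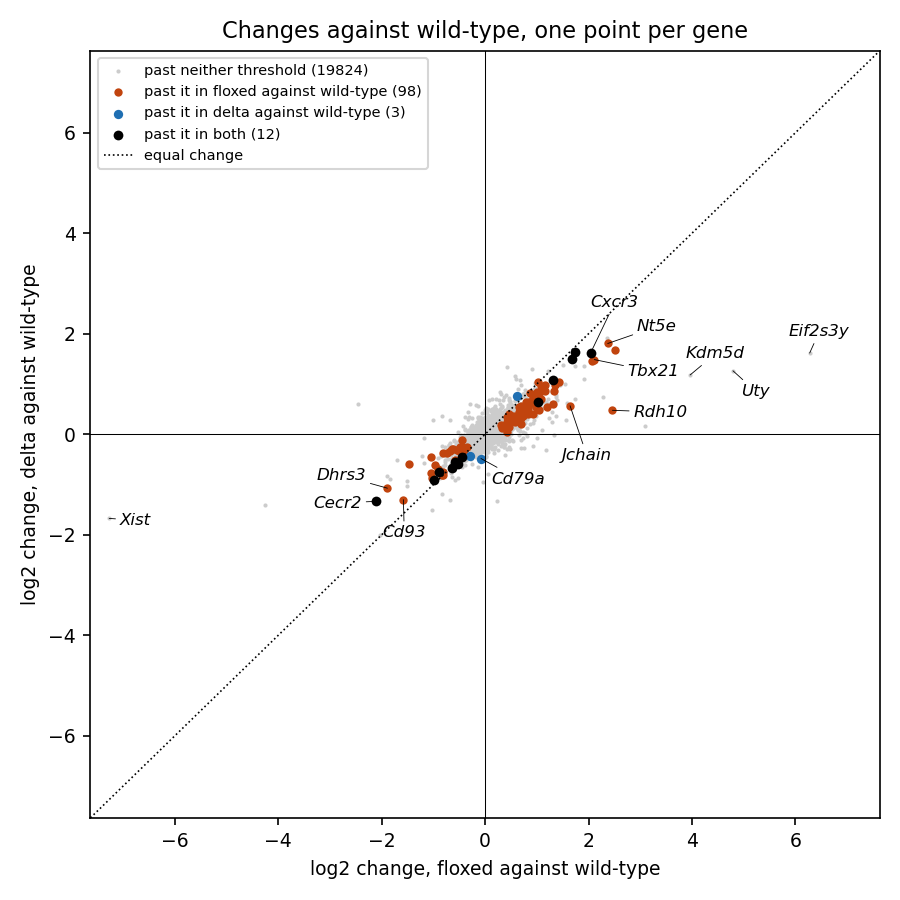
The log2 change of each of 19937 genes in floxed against wild-type (horizontal axis) and in delta against wild-type (vertical axis), with colours for genes past the threshold in floxed, in delta, in both or in neither, and a dotted line for equal change. The 12 genes past it in both lie in the same direction, Rdh10 lies far to the right at 2.46 and near 0.48 in delta, and Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty mark the unequal sex pattern of the groups.

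Delta against floxed arrays compared both transgenic genotypes directly. No group carried mb1-Cre without the transgene. Recombination of the transgene therefore cannot be told apart from the Cre insertion at Cd79a, here or in delta against wild-type. The sex pattern of the groups differed as well, and a gene that was not called was not shown to be equal in both. Rdh10 fell from an intensity of 2244 ± 489 (SD, n = 3) to 559 ± 17 (SD, n = 4), a log2 change of -1.98 (SE 0.11, 95% CI -2.23 to -1.73, adjusted p = 3.23e-05), and lay 0.48 above wild-type (adjusted p = 0.213). It was the 1 gene called by limma, where 1279 genes had an unadjusted p under 0.05, and it stayed past the threshold with each array left out. With sex as a covariate, which sets delta 1 alone against the floxed arrays and assumes its spread from the others, Rdh10 was at -2.02 (SE 0.18, adjusted p = 0.00770). Jchain was at -1.07 (SE 0.16, adjusted p = 0.123), with an intensity of 155 ± 19 (SD, n = 4) in delta.

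Other genes with small p-values in delta against floxed did not pass. Blvrb, which encodes a biliverdin reductase abundant in red cells, was at -0.45 (adjusted p = 0.123) and the interferon-induced exonuclease gene Isg20 at -0.57 (adjusted p = 0.153). Timm8a2 was at 0.42 (adjusted p = 0.123), Olfml3 at 0.57 (adjusted p = 0.203), and Rptn, Mir30e and Adam30 at 0.33, 0.48 and 0.70 (adjusted p = 0.528 each). The count of called genes was 10 without delta replicate 1, 4 without delta replicate 4, 2, 5 and 2 without floxed replicates 1, 2 and 3, and 2 without wild-type replicate 1.

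All 9 lists that camera called in delta against floxed were lower in delta. The proliferation list had a median of -0.12 over 25 genes, none past the threshold and 5 lower when adjusted over the list alone (adjusted p = 5.46e-10, and adjusted p = 0.0822 with an estimated correlation). In it the cyclin gene Ccna2 was at -0.45 (adjusted p = 0.469) and the mitotic kinesin gene Kif11 at -0.38 (adjusted p = 0.528). Markers of other cells were lower alongside. The T cell list had a median of -0.26 with 6 lower when adjusted over the list alone (adjusted p = 3.11e-08, and adjusted p = 0.198 with an estimated correlation), with Cd8b1 at -0.82 and Cd28 at -0.56. The erythroid list had a median of -0.41 with 6 lower when adjusted over the list alone (adjusted p = 2.09e-07, and adjusted p = 0.188 with an estimated correlation), with Alas2 at -1.48 and Trim10 at -0.70. The NK cell list had a median of -0.28 with 4 lower when adjusted over the list alone (adjusted p = 5.41e-07, and adjusted p = 0.188 with an estimated correlation), with Ncr1 at -0.63 and Klrd1 at -0.43.

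The marginal zone, B1 and age-associated B cell list was lower in delta than in floxed with a median of -0.33 (adjusted p = 3.08e-07, and adjusted p = 0.188 with an estimated correlation), with Anxa2 at -0.37 and Lgals1 at -0.41. The glycolysis list had a median of -0.10 (adjusted p = 0.000192, and adjusted p = 0.188 with an estimated correlation), with Aldoa at -0.19. The plasma cell list had a median of -0.08 with 1 lower when adjusted over the list alone (adjusted p = 0.00111, and adjusted p = 0.188 with an estimated correlation). The interferon list had a median of -0.07 (adjusted p = 0.00362, and adjusted p = 0.426 with an estimated correlation), with Rsad2 at -1.35. Log2 levels of Rsad2 were 7.04 to 8.99 in delta arrays, around the wild-type levels of 7.57 to 8.33. The MHC class II list had a median of -0.09 (adjusted p = 0.0460, and adjusted p = 0.540 with an estimated correlation), with H2-Oa at -0.21. With an estimated correlation camera called 0 lists, with 6 at an unadjusted p under 0.05, and fry called proliferation (adjusted p = 0.0430).

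Calls in delta against floxed ended for MHC class II genes without delta replicates 2, 3 or 4 or floxed replicates 2 or 3 (adjusted p = 0.0696, 0.106, 0.0693, 0.162 and 0.122). They ended for glycolysis without floxed replicate 2 (adjusted p = 0.0505) and for interferon genes without delta replicate 4 or floxed replicate 3 (adjusted p = 0.0693 and 0.103). The glycolysis mean was -0.05 without floxed replicate 2 against -0.10, and the T cell mean was -0.21 without floxed replicate 1 against -0.32. In the fit with sex, where delta 1 is the sole delta array compared, 8 lists were called, without interferon genes (adjusted p = 0.0652) and MHC class II genes (adjusted p = 0.398), with the immediate early list, in which delta 1 stands apart from the other delta arrays, called higher (adjusted p = 1.73e-11, and adjusted p = 0.176 with an estimated correlation). The erythroid mean was -0.85 in that fit, against -0.49. The 14 lists not called had camera adjusted p of 0.0945 for germinal centre, 0.121 for MYC and ribosome biogenesis, 0.141 for BCL6-repressed and 0.163 for immediate early genes. Mature follicular, pluripotency, myeloid and plasmacytoid dendritic cell genes each had 0.338, NF-kappaB targets 0.446 and pro-B and pre-B cell genes 0.504. The p53 list had 0.541, stem and progenitor and B cell receptor signalling genes 0.713 each, and chromatin genes 0.931. Median and mean differed in sign for the pro-B and pre-B cell list (0.01 and -0.02) and for the stem and progenitor list (0.02 and -0.04).

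**Figure D4:**
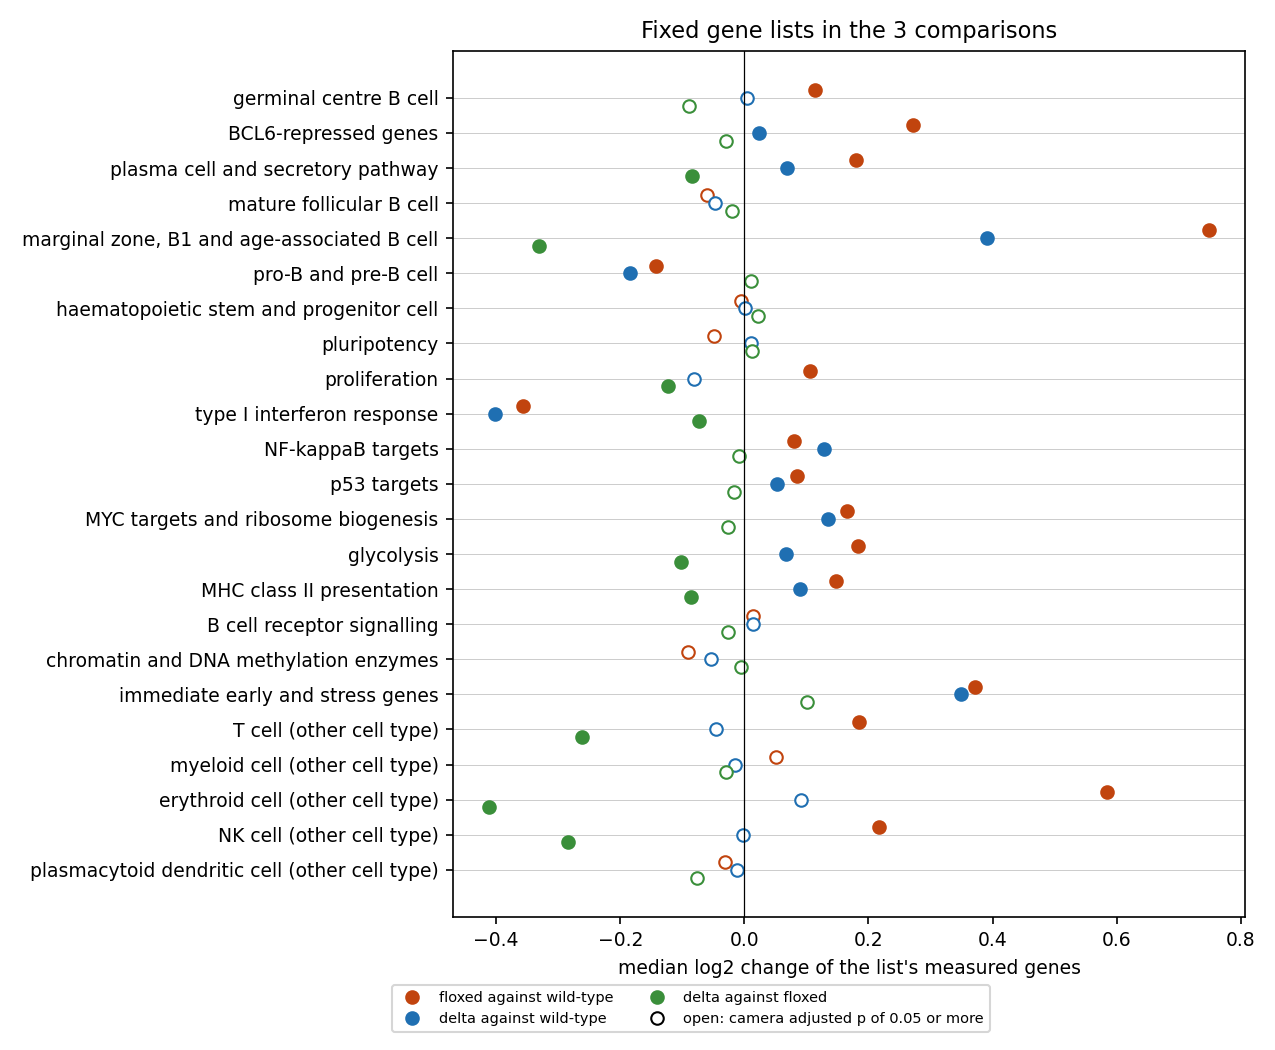
Median log2 change of the measured genes of each of 23 gene lists (vertical axis) in the 3 comparisons (colours), with filled points where camera with a preset correlation gave an adjusted p under 0.05 and open points elsewhere. The marginal zone, B1 and age-associated B cell list has the highest median in floxed against wild-type, 0.75, and the interferon list the lowest in delta against wild-type, -0.40.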

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

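The tests of the marginal zone, B1 and age-associated B cell genes and those with sex as a covariate were chosen after the result was seen. The tests of splits and of the neighbours of Rdh10 and Cd79a were written before, as was that of Rdh10 with the T cell covariate, although the covariate itself was chosen after the T cell markers were seen.

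The marginal zone, B1 and age-associated B cell genes were higher by a mean of 0.717 on the log2 scale over 20 genes in floxed and 0.394 in delta arrays. Myeloid cells left in the sort would raise the myeloid list as a whole if they carried all of its markers. A cell type that carries part of the list could leave the median unmoved. The median of the myeloid list was 0.0511 (95% bootstrap interval -0.0850 to 0.158) in floxed and -0.0158 (-0.0876 to 0.0498) in delta arrays. Bootstrap intervals here resample the genes of a list and do not measure the spread between arrays. The myeloid mean was 0.39, 0.07 and 0.06 above wild-type in floxed 1, 2 and 3, and -0.003, 0.06, 0.05 and 0.26 in delta 1 to 4. Floxed 1 and delta 4 lay beyond the wild-type arrays (-0.10 to 0.11). Cells that carry the whole list are thus argued against as the whole source in the other arrays alone. The list members Adgre1 (1.91 and 1.35) and Itgam (1.12 and 0.83) were higher without passing. Adgre1 lay at log2 levels of 9.11 to 9.83 in floxed against 7.09 to 7.81 in wild-type arrays. Myeloid cells rich in such members therefore stay open in all floxed arrays. T cells as the whole source are argued against less firmly. The mean stayed at 0.529 (0.0343 to 1.02) with the T cell markers as a covariate in floxed, though part of the floxed rise may come from T cells. In delta arrays the T cell list had a median of -0.0459 (-0.0827 to -0.00288). The NK cell list did not enter these tests. Its median was 0.22 in floxed and -0.003 in delta against wild-type, so NK cells stay open in floxed arrays. Sex cannot be told apart from genotype in floxed arrays, because the value with sex as a covariate, 0.866 (0.0926 to 1.64), rests on a single delta array of male pattern, whereas in delta the 3 arrays of female pattern, at 0.18, 0.27 and 0.85, all lay above the wild-type arrays of that pattern, at -0.11, 0.03 and 0.08, which argues against sex as the whole source there without excluding it, as their mean difference of 0.431 has an interval (-0.0153 to 0.878) that reaches 0. An effect of the transgene on the composition or state of B cells, and differences in age or housing of the mice, stay open and untested.

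Rdh10, higher in floxed than in delta and wild-type arrays, is the gene with the smallest p in both comparisons with floxed arrays. An insertion of the transgene beside Rdh10 that raises its neighbours is argued against by the 10 nearest tested genes, whose median change was 0.0218 (95% bootstrap interval over these genes -0.0374 to 0.154), with the highest at 0.281 in Sbspon, though an effect on Rdh10 alone was not tested. T cells are argued against by the change of 2.66 with their markers as a covariate (adjusted p = 1.46e-05), against 2.46 without. With sex as a covariate the change was 2.50 (95% CI 2.01 to 2.99), but this value rests on delta 1, so sex cannot be told apart from genotype from this fit, while delta 1, of male pattern, lay with the other delta arrays. The delta arrays, at log2 levels of 9.09 to 9.18, all lay above the wild-type arrays at 8.53 to 8.73, and no biological explanation was tested.

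Cd79a, lower in delta arrays, belongs to the locus that carries mb1-Cre. A chromosome segment carried with that locus was not seen among its 100 tested neighbours, of which 7 had an unadjusted p under 0.05 in delta against floxed, against 6.41% elsewhere (permutation p = 0.432). The neighbours were taken at any level, and genes that B cells do not express cannot show a segment, so a segment is not excluded. Sex is argued against as the whole source by the change of -0.486 (95% CI -0.628 to -0.343) in arrays of female pattern, against -0.482 in all, although the adjusted p then missed the threshold (0.0677). For this comparison the fit with sex equals that without delta 1. The change was kept, while the SE was 0.064 with 1 delta array fewer, against 0.057. Loss of an intact Cd79a allele to the Cre insertion is a candidate explanation that was not tested, as the arrays carry no allele information.

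Other splits of the arrays were counted for each comparison. In floxed against wild-type 1 of 10 splits, the real split, gave as many genes, with 110 against at most 2 in the others, and 10 splits are too few for a share under 0.05. In delta against wild-type 1 of 35 splits, the real split, gave as many genes, with 15 against at most 3 in the others. That is the smallest share that 35 splits can give. The real count was 0 with the 2 groups alone in the fit. It was also 0 without delta replicate 3, floxed replicates 1 or 3 or wild-type replicates 1 or 2, so chance is not excluded for the count. In delta against floxed 8 of 35 splits gave as many genes as the real value of 1, so chance cannot be excluded for the count. The highest of them, 31 genes, set delta 4 with the floxed arrays against delta 1 to 3, which points to a structure of the samples, and the split by sex pattern (delta 1 with the floxed arrays) gave 11.

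Among 68 delta groups of 4 arrays (45 genes and 23 lists), 9 held a sample far from the others, where chance gives about 1 in 20. All 68 use the same 4 arrays and some share genes, so they are not independent. The count therefore does not measure an excess over chance. Tbx21 was at 9.82 in delta 4 against 8.31 to 8.53 in the other delta arrays. Trabd2b was at 8.79 in delta 4 against 7.93 to 8.06. Nedd4 was at 9.07 in delta 3 against 9.51 to 9.55. Mir15a was at 8.66 in delta 3 against 8.18 to 8.24. Timm8a2 was at 5.95 in delta 1 against 6.04 in the others. The marginal zone, B1 and age-associated B cell list mean was 9.16 in delta 4 against 8.49 to 8.60. The interferon list mean was 8.25 in delta 2 against 7.98 to 8.02. The B cell receptor signalling list mean was 11.46 in delta 4 against 11.42 to 11.43. The T cell list mean was 7.10 in delta 4 against 6.80 to 6.84.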

How the results depend on the processing

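The T cell covariate, the fit with floxed replicate 2 as the sole floxed array and sex as a covariate were chosen after seeing the data, and the other alternatives before. Directions held for the named genes past the threshold under each alternative that left them tested (24 of 29 and 13 of 14 genes in the comparisons against wild-type with genes above the median level), while counts depended on the fit. Among all results and settings 1584 kept direction and side of the threshold or moved little, 561 lost and 5 gained the threshold, 62 moved and 4 reversed. Except where the number of genes or arrays changed by construction, the cause was not tested. The array signal over background was not measured, and the number of arrays limits what can be called.

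The count of genes changed, floxed against wild-type (110), was 193 with the 2 groups alone in the fit, 208 with array weights, 178 with arrays centred on their medians (148 higher and 30 lower, a larger share higher than the 78 and 32 reported), 18 with every probe set kept (16 higher and 2 lower), 32 at 2-fold or more, 188 with the replicate block, 10 with the T cell covariate, 2 with sex as a covariate and 6 with floxed replicate 2 alone. Leaving out each array in turn gave 18 to 240. For genes changed, delta against wild-type (15), the values were 0 with the 2 groups alone and 0 with floxed replicate 2 alone (limma, 1744 genes with an unadjusted p under 0.05 in each), 9 with trend and robust options, 3 with centred arrays (2 higher, 1 lower), 1 with every probe set, 5 at 2-fold, 6 with the replicate block and 3 with sex, and 0 to 23 with an array left out. For genes changed, delta against floxed (1), they were 2 with the 2 groups alone, 3 with trend and robust options and 2 with the replicate block, and 1 to 10 with an array left out, with Rdh10 called in each. The call of Cd79a in delta against wild-type also ended with the replicate block (-0.47, adjusted p = 0.116). The replicate numbers do not pair the arrays, since correlations of same-number arrays lay between -0.0828 and 0.121.

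For the overlap of the 2 comparisons against wild-type (12), the values were 2 with centred arrays, 0 with every probe set, 5 at 2-fold, 6 with the replicate block, 2 with the T cell covariate, 1 with sex, 0 with floxed replicate 2 alone and 0 to 21 with an array left out. The number of gene lists changed was 16, 11 and 9 in the 3 comparisons. It was 8 for floxed against wild-type with genes above the median level alone, 0 in each with an estimated correlation (7, 3 and 6 at an unadjusted p under 0.05), and 4, 2 and 1 with fry. Among the lists called and the Bcl6 level, reversed results were the immediate early list with sex as a covariate (-0.380), the T cell and NK cell lists with floxed replicate 2 alone (camera downward, at means of 0.00496 and 0.117), and Bcl6 level, floxed against wild-type, which lay between -0.299 without wild-type replicate 3 and 0.0437 without wild-type replicate 1.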

Other observations

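The test of mature follicular genes was chosen after the result was seen, and that of called genes along the chromosomes was written before.

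A first hypothesis was that fewer immature cells in the floxed samples raise all genes of mature B cells alike. The mature follicular list would then be higher by a share of the mean change of 0.717 in the marginal zone, B1 and age-associated B cell list. Its median was -0.0595 (95% bootstrap interval over its genes -0.100 to -0.0270), so no common rise was seen. The test cannot decide on fewer immature cells as such. List means of 12.3 to 12.4 in wild-type arrays were already high, and a small loss of immature cells might not move them. Cd93 (-1.58) and the pro-B and pre-B cell list (median -0.14) were lower. A further hypothesis was that background strain segments differ between the mouse groups, since the transgene was injected into eggs of a mixed CBAxC57BL/6J background. Called genes would then lie together on chromosomes, but 6 of 112 genes called against wild-type lay within 10 places of another, where 10000 random sets had a median of 12 (permutation p = 0.948). This covers segments that set whole groups apart, since genes that vary within a group have a wide shared spread. Zfp979 on chromosome 4 (-4.06) and Col6a4 and Cpne4 on chromosome 9 (-1.75 and -2.10) differed between delta 1 and the other delta arrays. Segments that vary between single samples were not tested and stay open.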
